A study of Saitozyma podzolica with 2 samples.

How the data were processed

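Total RNA of 2 cultures of Cryptococcus podzolicus Y3, 1 control and 1 grown with citrinin for 24 h, was made into TruSeq libraries and sequenced, per the labels' protocols. The labels state the citrinin dose once as 20 mg/L and once as 20 mg/mL. The groups were taken from the sample labels, and the direction of the ratio from the file header, which puts the citrinin sample over the control sample.

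The deposited comparison table holds a log2 ratio of citrinin over control, per the file headers as a ratio of FPKM, for each listed feature. Its false discovery rate, a p-value adjusted for multiple tests, was computed by the authors with a test that is not given in the sources used here. The other deposited file, per its header lines, holds the coding and protein sequence of each unigene and no expression value. Cufflinks is named in the submitters' processing notes, with no version. The identifiers are those of a Trinity assembly; the read aligner, the counting and the assembly settings are not given in the sources used here. The table lists 1208 features, with false discovery rates from 3.63e-24 to 0.00994, so features that did not pass cannot be counted or used as background. No genome was used, and no feature has a genome position.

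The log2 ratios were tested for being ratios of read counts. A ratio of (reads + prior) between the libraries, each over its own prior, was fitted to the table. The priors fitted apart for the libraries were 0.144 and 0.106 and summed to 0.25, as a prior of 0.125 reads per library of average size scaled to depth would. Their ratio gave the relative depth of citrinin over control, 1.367. Each log2 ratio was then searched for the pair of whole read numbers that gives it within the rounding of its printed decimals, with at most 20000 reads in the library with fewer reads. This gave whole reads for 1207 features (99.9%). For 1146 (94.9%) fewer than 0.05 matches were expected by chance. The other 61, at high read numbers, may be chance matches, so their log2 ratio is printed in place of reads and they are left out of sums of reads and of the plot of reads. After a random shift of each log2 ratio by up to 0.0001, 4.22% still matched at that level. On 1208 simulated features, 99.5% of read pairs came back exactly. These reads are inferred under that model and are not values of the table itself. Library totals are not known; the 1146 features sum to 1250744 reads in the citrinin and 1681809 in the control library. Of these 1146, 328 (28.6%) have under 100 reads over both libraries, and their folds are the least precise.

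Folds are ratios of recovered reads divided by the depth ratio, with exact 95% conditional intervals for 2 Poisson counts, which cover counting error only. Against 0 reads, a bound was computed from a floor of 3 reads per library. The false discovery rates were compared with a conditional negative binomial test of the recovered reads at fixed dispersions from 0.01 to 0.4. With a dispersion of 0.1 the number of features tested that each value implies was nearly constant (median 13971, 5th to 95th percentile 13636 to 14378). With 1 library per condition no test with a measured spread between cultures could be run. The fixed-dispersion test served only to find the dispersion that the authors' values imply and to count how many listed features pass at larger ones.

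Near-identical copies were found by aligning every coding sequence to all others with BLAST 2.17.0 (megablast, e-value 1e-10). A copy had at least 95% identity over at least 50% of the shorter sequence. Only coding parts were searched, so copies that share untranslated sequence alone were not seen. Other definitions (90% or 98% identity, or 30% of the shorter sequence) were tried as well.

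Gene lists were fixed, as were the design, the alternatives and the naming rule, before the data were examined. There are 24 gene lists, each a text pattern searched in the product descriptions from Swiss-Prot, nr, Pfam and KEGG in the table; the COG and KOG columns hold class names and were added only as an alternative. A list is described by its members higher and lower, its median log2 ratio, and the percentile of that median among 10000 random lists of listed features matched on reads in 5 strata. These percentiles describe the 2 libraries and are no test of the conditions. A percent has a 95% Wilson interval, which treats unigenes as independent and does not cover differences between cultures. Features named by rule were, among those with an annotation that names a function, the 10 highest and 10 lowest log2 ratios, and the highest and lowest such member of each list with at least 3 members; this gave 56 features, 36 of them with a near-identical copy. Other members named were chosen after their values were seen. Product names are those of the best match and not proof of function.

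Other settings chosen beforehand were a stricter adjusted p (1e-05), an absolute log2 ratio of at least 2, centring on the median, at least 10 reads in either library, annotated features only, coding sequences of at least 300 bases, other annotation text for the lists, and features with the same nr description counted once. The planned change of normalization and pseudocount was not run, because the table holds only features already past the authors' limit. Settings added after seeing the data were features without a near-identical copy, features with reads in both libraries, class names in the list text, and other dispersions. For the features named by rule, the ratio of recovered reads without a prior, or its bound, was added as well. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.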

Results

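Total RNA was sequenced from 2 cultures of the yeast Cryptococcus podzolicus Y3, an encapsulated soil basidiomycete also named Saitozyma podzolica. One culture had grown for 24 h in nutrient yeast dextrose broth (NYDB) and the other in the same medium with citrinin, a polyketide mycotoxin of Penicillium, Aspergillus and Monascus moulds that damages the kidney. The labels of the treated sample give the dose as 20 mg/L in one place and as 20 mg/mL in another, so the dose is certain only in its number. Each condition had 1 library, so no value below has a replicate check, and every difference is one between these 2 libraries. The comparison asked which transcripts differ when the yeast grows with citrinin. The authors' deposited table lists only the features past their own false discovery rate limit, 1208 of the 17075 assembled unigenes with a predicted coding sequence (7.07%). It gives no level or count per library, and the depth of each library is not stated. Reads per library are inferred here from its log2 ratios, 1207 of which gave whole reads in both libraries, and every read number and fold below rests on that inference. For the 1146 of them with fewer than 0.05 matches expected by chance, the median was 306.5 reads over both libraries (range 15 to 84427), with 1250744 reads in the citrinin and 1681809 in the control library, and the citrinin library was 1.37 times as deep as the control.

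Of the 1208 features in the authors' deposited table, 551 were higher and 657 (54.4%, 95% Wilson interval 51.6 to 57.2) lower with citrinin. That interval treats unigenes as independent, though many have copies, and does not cover differences between cultures, so it is no test of an excess of lower genes. The median log2 ratio in the authors' deposited table was 3.84 among the higher features and -3.93 among the lower ones, or 3.24 and -3.68 with the 264 features seen in 1 library set at their bounds. Fixed lists gather features by words in their annotation, protein domains included, so a count for a list also holds members that do not have its function by name. Members were mostly higher in the lists of major facilitator superfamily (MFS) and sugar transporters, glutathione metabolism, sulfur amino acid synthesis, and peroxisomes with fatty acid oxidation. They were mostly lower in the lists of iron and copper uptake, cell wall and capsule, and proteasome and ubiquitin. The smallest absolute log2 ratio in the authors' deposited table was 2.28, a 4.87-fold difference. Folds below are depth-scaled ratios of recovered reads with exact 95% intervals that cover counting error only, and a fold against 0 reads is a bound against 3 reads. The highest and lowest members of a list are named by log2 ratio in the authors' deposited table. For features with 0 reads in 1 library that order depends on the small number added to the reads, so such a member can have a smaller bound than the fold of another member. A feature with a near-identical copy elsewhere in the assembly may share reads with it, and its value is uncertain: this holds for 576 of the 1208 features, leaving 290 higher and 342 lower features without a copy.

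**Figure D1:**
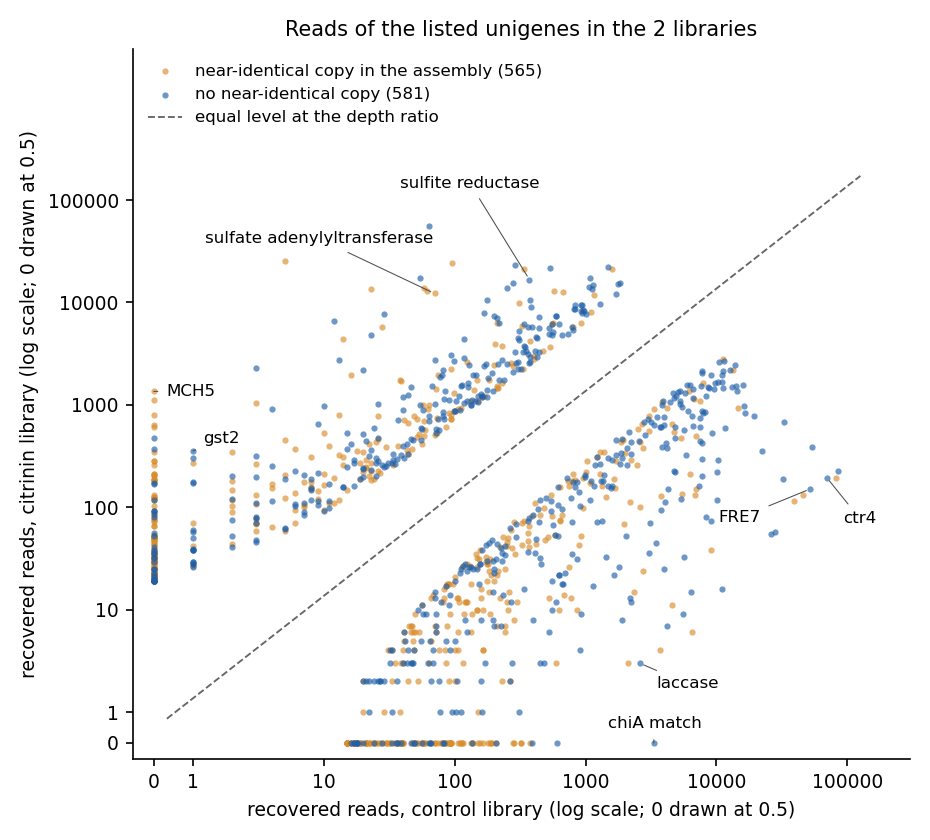
Reads inferred for 1146 listed unigenes, those with fewer than 0.05 matches expected by chance, in the control library (x axis, log scale) and the citrinin library (y axis, log scale), 1 point per unigene, with 0 reads drawn below 1. Orange points have a near-identical copy in the assembly and blue points do not; no point lies near the dashed line of equal level because the table lists only features past the authors' limit, and ctr4 and FRE7 lie far below the line with 69634 and 52068 control reads.

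The list of MFS and sugar transporters, which holds carriers of sugars, drugs, vitamins and other small solutes, was the largest fixed list, with 68 members higher and 37 lower. Their median log2 ratio in the authors' deposited table, 2.93 (2.88 with features seen in 1 library at their bounds), lay at or above those of all 10000 random lists of listed features matched on reads. The split was 38 to 21 without members that have a copy. Highest by log2 ratio, an order set by the 0 control reads and not by its bound, was a match of the maltose permease MAL61 (TRINITY_DN8984_c0_g1), with 91 reads against 0, at least 22.2-fold higher. A second MAL61 match (TRINITY_DN8286_c0_g1) was 194-fold higher (135 to 289), with 7678 reads against 29. Lowest was an unnamed MFS transporter (TRINITY_DN3756_c0_g1), with 6 reads against 6478, 1476-fold lower (678 to 4024), which has a copy. A match of the maltose permease MAL31 (TRINITY_DN4693_c0_g2) was 24.7-fold lower (22.1 to 27.8), so family members went both ways. The words of the list missed some carriers with an MFS domain. Among these was a riboflavin transporter MCH5 match (TRINITY_DN5117_c0_g2), which has a copy and stood at a log2 ratio of 13.2 in the authors' deposited table. In this and the following paragraphs, members that are not the extremes of their list were chosen after their values were seen.

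Amino acid and peptide transporters were divided, with 6 higher and 9 lower. The highest was an oligopeptide transporter 2 match (TRINITY_DN1595_c0_g1), with 1114 reads against 0, at least 272-fold higher, though it has a copy. The peptide transporter PTR2 match (TRINITY_DN8928_c0_g1), which has none, was 399-fold higher (228 to 772). The lowest was a match of the amino acid permease inda1 (TRINITY_DN6162_c0_g1), 651-fold lower (500 to 865), with 55 reads against 26201. The list's median lay at percentile 8.77 of the matched random lists, but at 86.9 without members that have a copy (4 higher of 7), so its direction depends on features with copies.

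All 6 members of the glutathione list, whose products join glutathione to foreign compounds or recycle it, were higher. Their median log2 ratio in the authors' deposited table was 4.92, at percentile 99.8 of the matched random lists (95.3 without copies), and 3 of them have no copy. A glutathione S-transferase 2 match (TRINITY_DN11291_c0_g1) had 355 reads against 1, a ratio of 260 (46.3 to 10283). A URE2 match with glutathione transferase domains (TRINITY_DN10421_c0_g1), highest by log2 ratio only because of its 0 control reads, had 185 reads against 0, at least 45.1-fold higher, and has a copy. For 3 of the 6 the best Swiss-Prot match was an unrelated protein, and membership rests on a glutathione transferase domain.

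The list of ABC transporters, the ATP-driven pumps that include drug efflux proteins, had 6 members higher and 3 lower, at percentile 94.4. Of the 6 higher ones only 3 are ABC proteins by name, so ABC proteins themselves were split 3 to 3. The others are 2 matches of a transcription factor and 1 of the MFS protein fnx1, which entered through multidrug resistance in their names. The 3 higher ABC proteins have no copy and the 3 lower ones have one. Of the 3 lower, 2 are unigenes of 1 assembly component (TRINITY_DN5011_c0_g1 and TRINITY_DN5011_c0_g2), not shown to be separate genes. Both matches of YOR1, a drug efflux pump of the yeast plasma membrane, were higher, by 12.0-fold (10.9 to 13.2) for TRINITY_DN1967_c0_g1 and by 20.0-fold (16.4 to 24.7) for TRINITY_DN7918_c0_g1. YCF1 (TRINITY_DN8142_c0_g1), which moves glutathione conjugates into the vacuole, was 8.80-fold higher (7.69 to 10.1). The highest member was not a pump but a match of a transcription factor, multidrug resistance regulator 1 (TRINITY_DN7049_c0_g1), with 171 reads against 0, at least 41.7-fold higher. The lowest, TRINITY_DN5011_c0_g2, was 63.0-fold lower (53.6 to 74.5) and has a copy.

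The list of dehydrogenases, reductases and oxygenases, made to find enzymes of foreign compounds, had 53 members higher and 36 lower, at percentile 98.7 of the matched random lists. Many of its members act on sugars or sugar alcohols by name, such as L-arabinitol 4-dehydrogenase, or entered through a domain only, such as FLO11 matches, so the count is not one of enzymes of foreign compounds. At an adjusted p under 1e-05 in the authors' deposited table, 10 were higher and 12 lower, so the direction of this list did not hold among its strongest members. A quinone oxidoreductase match (TRINITY_DN1596_c0_g2) was highest, at least 45.1-fold, and a phytanoyl-CoA dioxygenase (TRINITY_DN4231_c0_g3) lowest, at least 75.2-fold, both with a copy. An aryl-alcohol dehydrogenase match (TRINITY_DN7430_c0_g2) was 21.4-fold higher (18.7 to 24.6), and an aldehyde reductase 2 match (TRINITY_DN5771_c0_g1) was 837-fold lower (441 to 1832), with 9 reads against 5512. The list of esterases, lipases and other hydrolases was split evenly, 17 to 17. A tannase match (TRINITY_DN21_c0_g1) was highest among them, with 370 reads against 0, and a nuc-2 match (TRINITY_DN642_c0_g2) lowest, with 0 against 94 and a copy. Of the 3 cytochrome P450 features, which include 1 P450 reductase, CYP52A6 (TRINITY_DN3172_c0_g1) was 10.8-fold higher (8.33 to 14.2) and has a copy. The lowest (TRINITY_DN7645_c0_g1) was 12.9-fold lower (12.2 to 13.6). A single antioxidant feature passed the authors' limit, TRINITY_DN6129_c0_g2 with a thioredoxin domain, 6.76-fold higher (6.18 to 7.41).

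Sulfur amino acid synthesis had 7 members higher and 1 lower, at percentile 99.5 of the matched random lists. Among the 7 are 2 sulfate adenylyltransferase unigenes of 1 assembly component (TRINITY_DN3228) and 2 homocysteine S-methyltransferase unigenes of another (TRINITY_DN3239). They are not shown to be separate genes, and the percentile counts each of them. The sulfate permease match (TRINITY_DN2403_c0_g1), which takes up sulfate, was 80.0-fold higher (51.7 to 131), and sulfite reductase (TRINITY_DN95_c0_g1), which makes sulfide from sulfite, was 32.8-fold higher (29.6 to 36.5). These were the 2 members without a copy. Sulfate adenylyltransferase (TRINITY_DN3228_c0_g2), which activates sulfate, was highest at 128-fold (101 to 164), with 12245 reads against 70. The single lower member, a cystathionine beta-synthase match (TRINITY_DN7635_c0_g1), was 23.8-fold lower (14.2 to 43.1). The last 2 features have a copy.

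Of the 14 members of the list of peroxisomes and fatty acid oxidation, 13 were higher, at percentile 96.0 of the matched random lists (87.5 without copies), and 9 of the 13 have no copy. The log2 ratio in the authors' deposited table was 3.75 for isocitrate lyase of the glyoxylate cycle (TRINITY_DN8150_c0_g1), 2.86 for the peroxisomal thiolase POT1 (TRINITY_DN8083_c0_g1) and 2.97 for the membrane carrier PMP47A (TRINITY_DN8205_c0_g1). The 2 members named as carnitine acetyltransferases, CAT2 (TRINITY_DN7367_c0_g2) and YAT1 (TRINITY_DN8210_c0_g1), stood at log2 ratios of 2.59 and 2.84 in the authors' deposited table. An acyl-CoA dehydrogenase (TRINITY_DN7775_c1_g1) was highest, 66.3-fold (28.2 to 205), with a copy. A 3-hydroxyacyl-CoA dehydrogenase (TRINITY_DN779_c0_g1) was the 1 lower member, 6.99-fold (4.57 to 11.1).

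The list of glycolysis and the TCA cycle was split 6 to 6, and 2 to 3 without copies. Many of its members belong to other pathways by name, such as isocitrate lyase, transaldolase and homoisocitrate dehydrogenase. The split is therefore not one of glycolysis and TCA cycle enzymes. Pyruvate decarboxylase (TRINITY_DN7534_c0_g1), the first step from pyruvate to ethanol, was 10.4-fold lower (9.85 to 10.99). The highest member, an aldolase or citrate lyase family protein (TRINITY_DN9360_c0_g1), had 33 reads against 0, and the lowest, TRINITY_DN6988_c0_g1, had 1 read against 33, a ratio of 45.1 (7.55 to 1836). Of 10 respiratory chain features, 8 were lower, though several entered through a domain and are not respiratory proteins by name. They include the alternative oxidase (TRINITY_DN7210_c0_g1), 8.02-fold lower (6.51 to 9.96). The extremes of this list were a cytochrome b2 match (TRINITY_DN3145_c0_g1) with 0 reads against 28 and an ATP synthase subunit 9 match (TRINITY_DN886_c0_g1) with 20 against 0. The best nr match of the subunit 9 feature is a plant protein (Camellia sinensis), so its source is uncertain. All 3 features of the ergosterol list were lower, the lowest a sterol 24-C-methyltransferase match, ERG6 (TRINITY_DN2507_c0_g1), by 13.4-fold (12.1 to 14.8). The other 2, a sterol esterase and a sterol glucosyltransferase match, act on sterols and do not make ergosterol. The best nr match of the ERG6 match is a bacterial methyltransferase, so whether it makes ergosterol is uncertain too.

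The list of iron and copper uptake had 5 of 6 members lower, at percentile 0.33 of the matched random lists and with a median log2 ratio of -6.12 in the authors' deposited table. The copper transporter ctr4 (TRINITY_DN7350_c0_g1) had 195 reads against 69634 and was 488-fold lower (424 to 565). The ferric and cupric reductase FRE7 (TRINITY_DN7502_c0_g1), which reduces metal ions at the cell surface, had 151 reads against 52068 and was 472-fold lower (402 to 557). A laccase match (TRINITY_DN4147_c0_g1), a multicopper oxidase, had 3 reads against 2595, a 1183-fold difference (404 to 5739). The single higher member was another laccase match, laccase-5 (TRINITY_DN4364_c0_g2), with 305 reads against 1, a ratio of 223 (39.7 to 8838). None of these 4 features has a copy. The other 2, a GTPase match and an IMPACT homolog match, entered through a protein domain and do not take up metals by name. The laccase matches are oxidases and not uptake proteins by name, so only ctr4, a transporter, and FRE7, a metal reductase, bear on uptake.

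Cell wall and capsule features were mostly lower, 55 against 29, at percentile 10.6 of the matched random lists (21.6 without copies). The split was 32 to 17 without copies and 20 to 4 at an adjusted p under 1e-05 in the authors' deposited table. The lowest listed feature of all was a match of endochitinase A (TRINITY_DN2985_c0_g3), with 0 reads against 3316, at least 1511-fold lower, with no copy and no protein domain recorded. A chitin deacetylase (TRINITY_DN5054_c0_g2), which turns chitin into chitosan, had 195 reads against 81674 and has a copy. A glucan 1,3-beta-glucosidase match (TRINITY_DN4602_c0_g1) was 236-fold lower (168 to 343). Other matches of chitin deacetylase and of glucan 1,3-beta-glucosidase were higher, so both enzymes went both ways. The highest member was a DAN4 match (TRINITY_DN2211_c0_g2), with 123 reads against 0 and a copy. Its best nr match is an inositol oxygenase, so it is likely not a cell wall protein. Many of these names rest on repeat-rich best matches: FLO11, a yeast flocculin, was the best Swiss-Prot match of 83 listed features, 39 higher and 44 lower.

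Ribosomal protein features were higher in 9 of 12 cases and ribosome biogenesis features in 12 of 16, at percentiles 77.6 and 83.7 (73.1 and 74.7 without copies). The ribosomal protein matches S4 (TRINITY_DN11133_c0_g1) and S0 (TRINITY_DN2987_c0_g1) were 6.13-fold (5.73 to 6.56) and 6.97-fold higher (6.24 to 7.80). Highest by log2 ratio, through their 0 control reads, were ribosomal protein L5 (TRINITY_DN1678_c0_g2), with 19 reads against 0 and a bound of only 4.63-fold, and the RNA polymerase I subunit RPA12 (TRINITY_DN3741_c0_g1), with 48 against 0. The best nr match of the L5 feature is a plant protein (Prunus persica), so its source is uncertain. Lowest were the ERG6 match, which entered through a ribosomal protein methyltransferase domain, and a nucleolar complex protein 14 match (TRINITY_DN4945_c0_g5) with 0 reads against 17, which has a listed copy that was higher. Other unigenes of its assembly component (TRINITY_DN4945_c0_g2 and TRINITY_DN4945_c0_g4) count among the higher features, so these are not shown to be separate genes. Only 3 of the 16 biogenesis features were higher and without a copy. The list of translation factors and tRNA ligases was split 6 to 7. By name, 4 of the lower members (2 matches of the transcription factor SPT5, fzo1 and ypt3) and 1 of the higher (slp1) are neither, which leaves 5 higher and 3 lower. A mitochondrial histidine tRNA ligase match (TRINITY_DN3279_c0_g1) had 480 reads against 0 with no copy, at least 117-fold higher, and a phenylalanine tRNA ligase match (TRINITY_DN3389_c0_g1) had 0 against 39.

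Proteasome and ubiquitin features were lower in 7 of 7 cases, at percentile 4.91, and 2 of the 7 have no copy. Their median log2 ratio in the authors' deposited table was -5.36, or -4.19 with 3 features at their bounds. The lowest was an E3 ubiquitin ligase match, dbl4 (TRINITY_DN6056_c0_g2), with 0 reads against 150 and a copy. The proteasome subunit beta type-5 (TRINITY_DN6358_c0_g1), without a copy, was 11.2-fold lower (5.96 to 23.2). The list of proteases had 18 members higher and 6 lower, at percentile 96.4, but 6 to 3 and at percentile 67.7 without copies. Many of the higher members are not proteases by name, among them 2 matches of the transcription factor prtT, 2 of a tRNA threonylcarbamoyltransferase and 2 of FLO11, so the direction of proteases themselves stays open. The highest was a carbamoyl-phosphate synthase match (TRINITY_DN469_c0_g2), which is not a protease and entered through a peptidase domain. The lowest was methionine aminopeptidase 1 (TRINITY_DN6854_c0_g2), with 0 reads against 15. The metalloprotease YME1 (TRINITY_DN7892_c0_g1) stood at a log2 ratio of 3.98 in the authors' deposited table.

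DNA repair and replication features were lower in 8 of 9 cases, at percentile 3.13, with a median log2 ratio of -4.92 in the authors' deposited table, or -3.11 with 2 features at their bounds. Of the 9, 3 are matches of the transposon Ty5 and 1 is a reverse transcriptase. Among the others, the mismatch repair protein MSH3 (TRINITY_DN5911_c0_g2) was 31.5-fold lower (11.9 to 118) and the helicase PIF1 (TRINITY_DN6635_c0_g1) 5.09-fold lower (4.58 to 5.65). Replication factor C subunit 5 (TRINITY_DN2255_c0_g1) had 0 reads against 19, and the reverse transcriptase (TRINITY_DN1479_c0_g2) was 7.31-fold higher (3.93 to 15.1), both with a copy. Mobile elements were split 4 to 5, from a SLACS match (TRINITY_DN8221_c0_g1) with 23 reads against 0 to a Ty5 match (TRINITY_DN8275_c3_g3) with 1 against 111. The cell cycle list, which holds YCF1 and others not of the cell cycle by name, was split 6 to 5. A cyclin-domain feature matched to a CTD kinase subunit (TRINITY_DN7869_c0_g1) stood highest, at a log2 ratio of 5.28 in the authors' deposited table, and a PHO85 match (TRINITY_DN9260_c0_g2) lowest, with 0 reads against 322 and a copy. Heat shock proteins and chaperones were split 5 to 3. Of 3 small heat shock protein 16 matches, TRINITY_DN240_c0_g1 was 23.5-fold lower (21.5 to 25.7), TRINITY_DN8217_c0_g1 stood at a log2 ratio of -3.59 in the authors' deposited table, and TRINITY_DN7905_c0_g2 was 5.95-fold higher (4.87 to 7.33). The highest of the list was a two-component histidine kinase match (TRINITY_DN6647_c0_g1), 26.2-fold (15.7 to 47.1), not a chaperone by name.

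**Figure D2:**
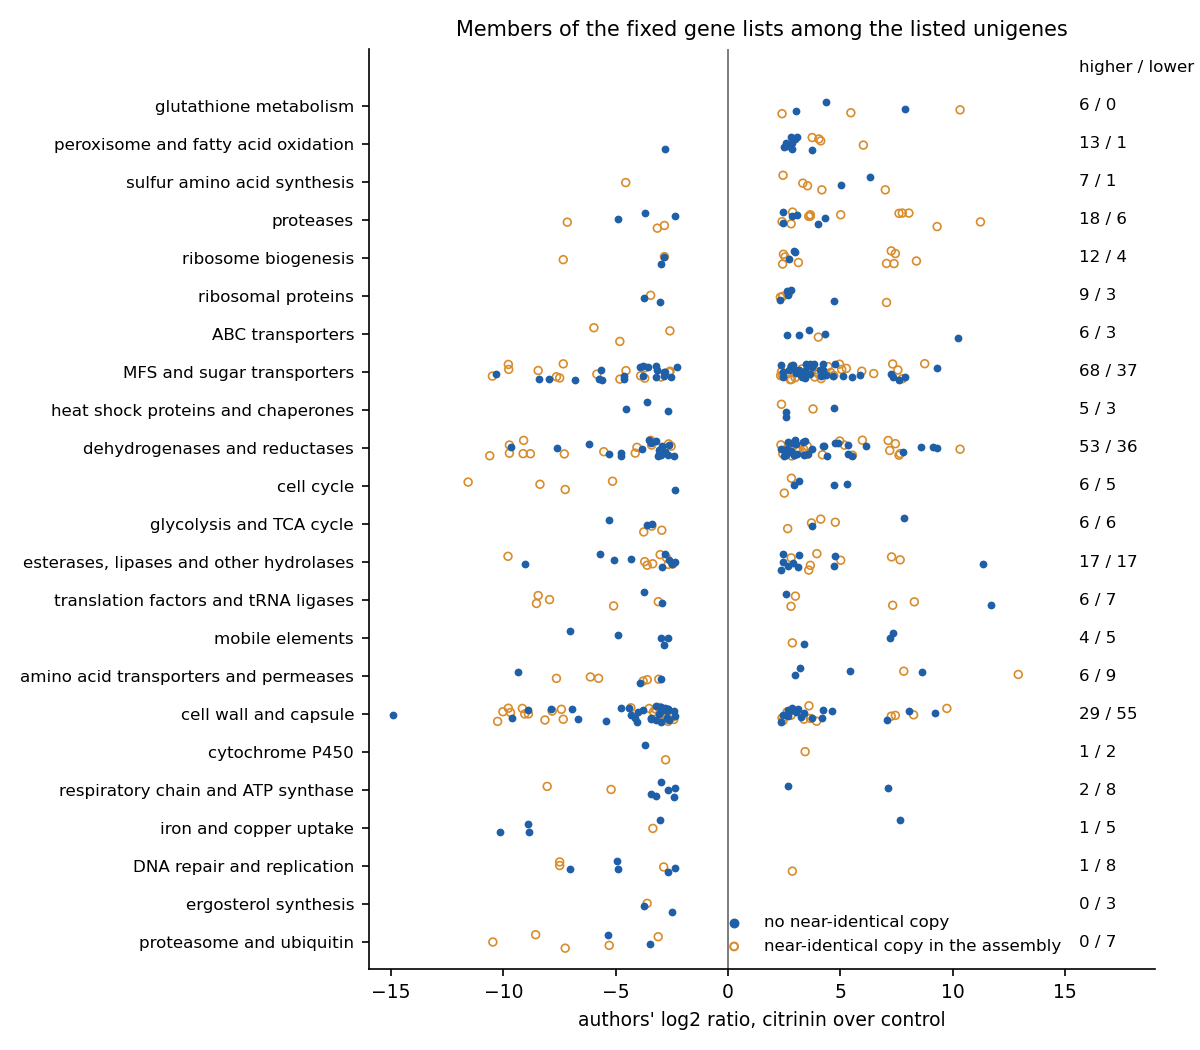
Log2 ratio of citrinin over control in the authors' deposited table (x axis) for the members of each fixed gene list with at least 3 members (y axis), 1 point per listed unigene, filled blue without and open orange with a near-identical copy. The numbers at the right count higher and lower members, from 6 against 0 for glutathione metabolism to 0 against 7 for the proteasome; the gap around 0 is set by the authors' limit.

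The 20 features with a named function that lay highest and lowest by log2 ratio in the authors' deposited table all had reads in 1 library only. That order depends on the small number added to the reads: by the folds printed above, ctr4, inda1 and others with reads in both libraries differ by more than several of the bounds. The 10 highest were matches of the riboflavin transporter MCH5 (TRINITY_DN5117_c0_g2, 1354 reads against 0, at least 330.1-fold higher), oligopeptide transporter 2, FLO11 (TRINITY_DN6618_c0_g2), a DUF218 domain protein (TRINITY_DN5884_c0_g3), the histidine tRNA ligase, the tannase, the carbamoyl-phosphate synthase, a serine and arginine repeat protein, the nuclear distribution protein nudE and alpha-galactosidase G. The 10 lowest were matches of endochitinase A, the protein kinase ran1 (TRINITY_DN3317_c0_g1, 0 reads against 600, at least 273-fold lower), the kinase PHO85, dihydroxyacetone synthase, the pantothenate transporter FEN2, FLO11 (2 features), a CFEM domain protein, SEC31 and a bZIP transcription factor. The best nr match was a transketolase for the dihydroxyacetone synthase match and a Het-C domain protein for the SEC31 match, so these 2 names are uncertain. One of the 2 lower FLO11 matches (TRINITY_DN6618_c0_g4, 0 reads against 280) is a near-identical copy of the higher one (796 against 0), and their summed reads differed by a log2 ratio of only 1.06, so they may not be separate extremes. Only 4 of these 20 lack a near-identical copy: the histidine tRNA ligase, the tannase, the endochitinase A match and ran1.

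Reads in 1 library only were found for 264 features, 136 in the citrinin library and 128 in the control library. Of these, 78.4% (Wilson interval 73.1 to 82.9) had a near-identical copy, against 39.0% (36.0 to 42.2) of features with reads in both libraries and 33.7% of all unigenes. Listed copies formed 123 pairs, and in 18 of them the copies went in opposite directions. For the DUF218 protein, 1 copy (TRINITY_DN5884_c0_g3) had 632 reads against 0 and another (TRINITY_DN5884_c0_g1) 10 against 622, so that their summed reads differed by a log2 ratio of -0.41. One more listed copy (TRINITY_DN5884_c0_g2) had 120 reads against 0. Its sum with the lower copy alone differed by -2.71, but that sum leaves out the reads of TRINITY_DN5884_c0_g3. It therefore cannot test a split among all of these copies. The sums stayed within 1 log2 unit of 0 in 5 of the 18 pairs. Several pairs share a unigene and so are not separate, and a sum over 1 pair leaves out the reads of any further copies.

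**Figure D3:**
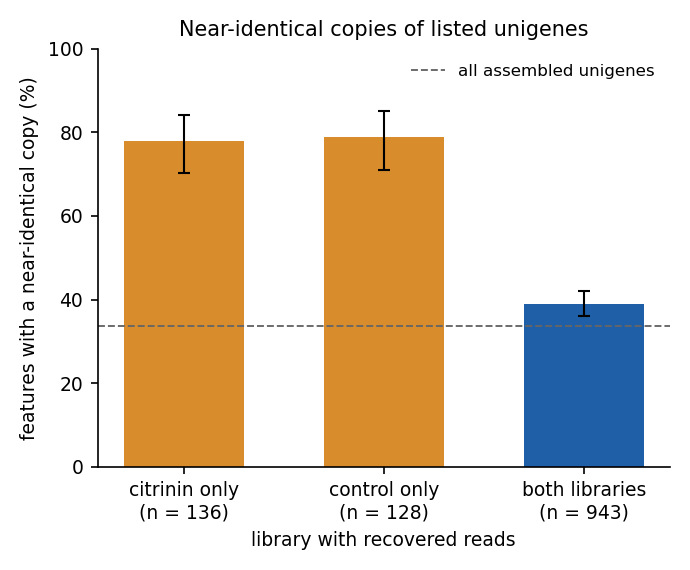
Percent of listed unigenes with a near-identical copy among the assembled coding sequences (y axis), by the library in which reads were recovered (x axis), with 95% Wilson intervals as bars. Features with reads in 1 library reached 77.9% and 78.9%, against 39.0% with reads in both, and the dashed line marks 33.7% for all unigenes.

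The listed features had longer coding sequences than the assembly as a whole, with a median of 882 against 555 bases, and close GC content, 60.3% against 59.8%. Their best nr matches lay in the Tremellomycetes, the class of this yeast, for 755 features (62.5%), 452 of them in Cryptococcus and 206 in Tremella. Non-fungal best matches made up 11.7% (Wilson interval 9.98 to 13.6), 49 of them bacterial. Among all 1208 features, 200 had no annotation that names a function.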

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

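The tests in this part were all chosen after the results they bear on had been seen.

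Features with reads in 1 library only stood out in the unigene sequences, which are outside the table of expression ratios: 78.4% of the 264 had a near-identical copy, against 39.0% of features with reads in both libraries. RNA of an organism outside the Tremellomycetes in 1 library is argued against as the whole source, since 60.2% (54.2 to 65.9) of their best matches lay in that class, against 63.1% for features with reads in both libraries. Reads shared or split between copies may account for many of them, because the share with a copy was above that of the other features with intervals that do not overlap. In only 16 of the 264 was a listed copy found going the opposite way, which alone does not show a split. The summed reads stayed within 1 log2 unit of 0 in 5 of the 18 opposite pairs. Several of these pairs share a unigene, such as TRINITY_DN8097_c0_g1, and a sum over 1 pair leaves out the reads of any further copies. The pairs therefore do not measure how often a split occurred. For the 57 without a copy the cause stays open: 54.4% (41.6 to 66.6) had another unigene in the same assembly component, against 39.1% (35.2 to 43.2) of features without a copy and with reads in both libraries, and a true difference in expression was not tested.

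The second pattern is the unit of the ratios: those of FPKM with nothing added are argued against by the divisors fitted apart for ratios above and below 1, whose product, 0.0152, would be at least 1 if each were a whole read. A constant added to FPKM would be worth more reads in a longer unigene, but of 315 log2 ratios beyond 7 in the authors' deposited table, those worth under 400 reads against 0, 257 (81.6%, 76.9 to 85.5, against 1% by chance) lay within 0.005 reads of 1 common step, over coding lengths from 99 to 3513 bases. The values are consistent with read counts with a small prior added, since 99.9% gave whole reads, 94.9% with fewer than 0.05 chance matches expected against 4.22% at that level after a random shift, and the largest ratios, against 0 reads, depend on that prior. The false discovery rates fit a fixed dispersion of 0.1, with an SD of 0.01002 in the log10 of the implied number of features tested, against 0.415 at 0.09 and 0.336 at 0.11. A fixed dispersion stands in for the spread between cultures, which 1 library per condition cannot give, so how many features would pass with replicates is open.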

How the results depend on the processing

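The alternatives on copies, reads in both libraries, class names, dispersion and ratios without a prior were chosen after the results had been seen. The count of listed features (1208, 551 higher and 657 lower) changed little under 5 of the planned settings, down to 1124 with coding sequences of at least 300 bases. Of these, an absolute log2 ratio of at least 2 and at least 10 reads removed no feature and so tested nothing, and centring on the median of -2.52 gave equal numbers by construction. It fell to 368 (142 and 226) at an adjusted p under 1e-05, by the stricter limit itself, and to 632 (290 and 342) without near-identical copies. With a fixed dispersion of 0.16 it was 650 (278 and 372), with 0.2 it was 443 (177 and 266), and with 0.4 it was 73 (26 and 47). More features were lower than higher under each of these settings apart from the centring. Among 161 alternatives of list directions, 144 stayed within the Wilson interval of the main percent of members higher, and 17 moved. None of the directions whose interval excludes 50% turned, and 31 more alternatives had fewer than 3 members and gave no value. The 144 include the absolute log2 ratio of at least 2, which left the lists unchanged and so tested nothing. Most others use a part of the same members, so staying within a wide interval says little about how stable a direction is. The percent of members higher moved for ABC transporters from 66.7 to 33.3 with nr text only and to 100 without copies, and for dehydrogenases from 59.6 to 45.5 at an adjusted p under 1e-05. It moved for esterases from 50 to 16.7 with Swiss-Prot text and to 33.3 with nr text, and for the cell cycle from 54.5 to 25 with nr text and to 80 without copies. It went for DNA repair from 11.1 to 0 with Swiss-Prot text, at an adjusted p under 1e-05, with each nr description counted once and without copies. It rose for glycolysis from 50, for peroxisomes from 92.9 and for proteases from 75 to 100 at an adjusted p under 1e-05, and for peroxisomes also to 100 with Swiss-Prot text. For the cell wall it fell from 34.5 to 7.69 with nr text and to 16.7 at an adjusted p under 1e-05. The number of lists whose interval excludes 50% fell from 9 to 2 with nr text only, to 4 at an adjusted p under 1e-05 and to 5 without copies, each with fewer members. The median coding length rose from 882 to 925.5 bases when sequences under 300 bases were left out, by construction. The cause was not tested for the list changes. Of the 56 features named by rule, 40 had an adjusted p under 1e-05 and 42 passed at a dispersion of 0.2. Without a prior, or at their bounds, all 56 kept their sign, a result that ratios of this size all but fixed beforehand. The planned change of normalization and pseudocount was not run. No paired analysis was possible because each condition has 1 library. Depth limits the features under 100 reads most.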

Other observations

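The sets and tests in this part were all chosen after the values had been seen. Calcium was named in the annotation of 9 listed features, and all 9 were lower with citrinin. They include the vacuolar calcium exchanger VCX1 (TRINITY_DN7783_c0_g1), at a log2 ratio of -5.51 in the authors' deposited table. For 2 of the 9 the best nr match is a sodium or potassium ATPase, so their ion is uncertain. One of these is the cta3 match (TRINITY_DN6126_c0_g1), 85.6-fold lower (77.1 to 95.3). Of 7 features with copper or laccase in their annotation, 6 were lower. Besides ctr4, FRE7 and a laccase these are 3 copper amine oxidase unigenes of 1 assembly component with the same nr match, so they are not shown to be separate genes. One of them, TRINITY_DN8110_c0_g1, was 60.6-fold lower (50.6 to 73.3). Phosphate uptake went both ways. A pho-4 type phosphate permease (TRINITY_DN3353_c0_g1) had 16 reads against 10958 and was 937-fold lower (576 to 1639), while a high-affinity phosphate permease match (TRINITY_DN4871_c0_g1) had 5731 reads against 387. The aldose 1-epimerases of galactose metabolism, TRINITY_DN4072_c0_g1 and TRINITY_DN3992_c0_g1, were 48.4-fold (43.0 to 54.5) and 38.7-fold lower (32.9 to 45.8).

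Among higher features outside the fixed lists, a 3-beta hydroxysteroid dehydrogenase family protein (TRINITY_DN8172_c0_g8) had 55319 reads against 64 and was 632-fold higher (495 to 821). Its best nr match is a bacterial protein (Amycolatopsis orientalis), so its source and function are uncertain. An allantoate permease (TRINITY_DN7063_c0_g2), for a nitrogen source, had 2267 reads against 3, a ratio of 553 (189 to 2682). Its coding sequence has only 225 bases. An MFS feature of the same component (TRINITY_DN7063_c0_g1) stood at a log2 ratio of 8.75 in the authors' deposited table, so they are not shown to be separate genes. An allantoate transporter match (TRINITY_DN9628_c0_g1) stood at 3.49 there and another allantoate permease (TRINITY_DN1708_c1_g1) at -3.94, so these carriers went both ways. A nitrilase match (TRINITY_DN5006_c0_g2) was 154-fold higher (90.1 to 290.1). The succinate and fumarate carrier SFC1 (TRINITY_DN6934_c0_g1) stood at a log2 ratio of 3.52 in the authors' deposited table. An FMN reductase match, LOT6 (TRINITY_DN3918_c1_g1), was 28.3-fold higher (22.4 to 36.3), and a xylosylphosphotransferase match (TRINITY_DN6199_c0_g2) 23.7-fold higher (17.7 to 32.6). Thiamine thiazole synthase (TRINITY_DN6167_c0_g1) was 94.8-fold lower (64.5 to 145), and a berberine bridge family oxidase (TRINITY_DN7145_c0_g1) 660-fold lower (510 to 869). Apart from the MFS feature and the other allantoate carriers, for which copies are not given here, none of these features has a near-identical copy. By KOG class in the authors' deposited table, translation had 22 features higher and 6 lower (11 and 1 without copies), energy production 19 and 9, signal transduction 15 and 21 (3 and 13 without copies), and chromatin structure 0 and 7, of which 2 have no copy.

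For the copper and calcium features, reads shared between copies are argued against as the whole source, since only 46.2% (6 of 13, 23.2 to 70.9) of the assembly components of the 15 lower features had any alignment of at least 90% identity to another coding sequence, and for these 6 they stay open, as 0 had a listed copy going the opposite way and unlisted copies have no values. How unusual the shared direction is stays uncertain too: with 1 feature per component, no copies and no uncertain ATPases, 7 of 8 were lower (87.5%, 52.9 to 97.8), against 54.1% of all listed features without a copy. A more alkaline medium in the control culture is a candidate explanation, because fungi are known to raise copper and iron reductases and calcium signalling at alkaline pH. The phosphate permeases named above went both ways, but they are of different types by name and do not decide it. Of 6 features gathered for the pH response, not all of them named for it, 100% were lower, which leaves the explanation open: 2 are RIM101 unigenes of 1 component (TRINITY_DN3181_c0_g2, log2 ratio -5.39 in the authors' deposited table), 2 are SUR7/PalI domain features with the same nr match, CRZ1 (TRINITY_DN2665_c0_g1, 13.9-fold lower, 10.3 to 19.1) belongs to calcium signalling itself, 1 is a phosphoesterase of the calcineurin type, and only 2 have no copy. An effect of citrinin and any difference between the cultures other than citrinin, such as growth stage or pH, cannot be told apart with 1 culture per condition.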
